A study of Glycine max with 2 samples.

How the data were processed

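Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole seeds of soybean (Glycine max, cultivar Williams 82) that held embryos at the globular stage, an early stage in which the embryo is a ball of cells without cotyledons. Per the labels' protocols, seeds 1.0 to 1.5 mm long were crosslinked in 1% formaldehyde for 10 min, chromatin was sonicated to fragments of 100 to 500 bp, and 10 µg of a rabbit antibody raised against a peptide of the soybean YAB1-like protein was used for the immunoprecipitation. YAB1-like belongs to the YABBY family, plant transcription factors known for their part in the polarity of leaves and other lateral organs. Libraries were amplified with 15 PCR cycles. The samples used here were 1 ChIP library and 1 input library (total chromatin without immunoprecipitation), both of replicate 1. The second replicate that the series design mentions was not analysed here, and no file of the input library was used. Which library the caller took as its control is not given in the sources used here, so the control below is not assumed to be this input.

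The measurements were 1 list of peaks in narrowPeak format. Per the submitters' processing notes, Bowtie 0.12.7, SAMtools 0.1.18 and MACS2 were used. Alignment settings, the treatment of duplicate reads, the calling command and the genome build are not given in the sources used here. Peak names in the deposited file carry 1 replicate and 1 run, which points to calling on this library alone but does not show it. The names are numbered without a gap and without letter suffixes, so nothing in the numbering shows that peaks were removed before deposit or split at sub-summits. The deposited fold of each peak is a ratio of the ChIP pileup (overlapping extended fragments) to the expected pileup at the summit, as the peak caller wrote it. The deposited −log10 values are the caller's p-value and q-value, and the deposited score differs from 10 times the −log10 q-value, cut to a whole number, by at most 1. The lowest −log10 q-value in the list was 2.03. These values are the authors' and were used to describe, rank and filter peaks within the list. Coordinates are given 1-based on the sequences of the peak file, 20 chromosomes and unplaced scaffolds, whose build is not named.

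Fragment counts behind each peak were recovered from the deposited fold and p-value together. Under the scoring MACS2 is known to use, the fold is (pileup + 1)/(expected pileup + 1) and the p-value is the upper Poisson tail of the pileup. A whole ChIP pileup matched the deposited −log10 p-value within 0.0001 for 100% of the 31461 peaks, while the next-best whole number missed by at least 0.0567. In 2000 simulated peaks this inversion returned 100% of the true pileups, and it accepted 0% of 2000 simulated pileups that were off by 0.5 fragment. The expected pileups then took only 4 forms. They lay at a genome-wide floor of 3.08 fragments in 5649 peaks, on multiples of 0.481 in 10894 peaks, on multiples that fit a 1 kb window in 8048 peaks and on multiples that fit only a 10 kb window in 6870 peaks, and 0 peaks were left over. A value counted as a multiple when it lay within 0.0004 fragments of one (0.0005 for the floor). The step of a 10 kb window is 0.0118 fragments, so 6.75% of arbitrary values would pass at that step. These steps show that a control library was used and scaled down to the ChIP library, that the control held 2.08 times as many retained reads, and that fragments were extended to 246 bp, the smallest peak width. The floor corresponds to 12.5 ChIP reads and 26.0 control reads per kb of the genome size given to the caller. Total reads cannot be stated because that genome size is not given in the sources used here. Ratios below are pileup over expected pileup without a pseudocount. Their 95% intervals are exact Poisson (Garwood) intervals of the ChIP pileup, with the expected pileup taken as fixed, and shares have Wilson 95% intervals. The Wilson intervals treat peaks as independent, although peaks were grouped along the chromosomes, so they are too narrow as a spread between regions. PCR fragments without molecular identifiers are not independent molecules, so these intervals cover counting error only.

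Peak density was counted in 1 Mb windows from the start of each chromosome to its last peak end, and compared with 200 placements of the summits at random along their own chromosome. Spacing was the share of neighbouring summits within 2 kb and the share of peaks in chains of such summits, compared with 1000 placements at random within each summit's own 1 Mb window. The likeness of neighbours was the Spearman correlation of fold between neighbouring peaks within 10 kb, compared with 1000 shuffles of fold within chromosomes. Differences of median fold were tested with 10000 random permutations of the peaks, and relations across the 20 chromosomes with 100000 permutations and Benjamini-Hochberg adjustment over 3 relations. All tests were two-sided unless stated. On simulated data the spacing ratio was 0.977 for summits placed at random and 1.63 when 10% of 31258 summits were given a partner 1 kb away. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

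Before the data were examined, tests of promoters, 30 gene lists and 22 sequence motifs were fixed, together with the rule for regions named in the text. The rule named the 10 peaks of highest fold where no annotation of the build is at hand. The promoter, gene list and motif tests were not run, because no genome sequence was used here and the gene table at hand is of the assembly Glycine_max_v4.0, which no source names for the peaks. With that table, 26.57% of summits lay within 1 kb of either end of a protein-coding gene, against 26.62% to 27.8% when all summits were shifted by 50 to 500 kb, so summits were not enriched at its gene ends. A different build or binding away from gene ends would both give this, and as no source names the build of the peaks, they were not assigned to genes. The tests of density, spacing and neighbouring fold were chosen after the peak list was seen. There is 1 peak list here and no second replicate was used, so no comparison between samples was possible, and p-values describe the arrangement of peaks within this list.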

Results

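ChIP-seq with an antibody against the YAB1-like protein was done in whole soybean seeds with globular-stage embryos. The aim was to locate the sites that this transcription factor occupies early in seed development. Peaks are called sites of binding below. No motif test, second replicate or check of the antibody was used here, so occupancy by this protein is assumed. The data were 1 list of 31461 peaks from the ChIP library of replicate 1, called against a control library. Of these peaks, 31258 lay on the 20 chromosomes and 203 on 44 unplaced scaffolds. Peaks covered 13.8 Mb in all and 1.45% of the chromosome span. The ChIP library held 12.5 retained reads per kb and the control 26.0 per kb of the genome size used by the caller. The median peak rested on 20 overlapping ChIP fragments at its summit (95% Poisson interval 12.2 to 30.9), and the smallest on 12 (6.20 to 20.96). No second replicate was used here, so all intervals describe counting error in this library. Those of ratios leave out the counting error of the control. None of the intervals covers selection. Each pileup was read at the summit of a peak that had passed the cutoff, and the strongest peaks were picked for high fold. Pileups and ratios may therefore be overstated, most of all for the strongest peaks.

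The strongest binding was on chromosomes 18 and 8. The peak of highest fold covered 57421417 to 57422508 on chromosome 18, near the last peaks of that chromosome, and its summit held 198 ChIP fragments where 3.85 were expected, a ratio of 51.4 (95% interval 44.5 to 59.1). The next lay at 47622420 to 47623790 on chromosome 8, with 164 fragments and a ratio of 48.7 (41.5 to 56.7). A peak at 3215360 to 3216480, near the opposite end of chromosome 8, had 130 fragments and a ratio of 42.2 (35.3 to 50.1). The fourth, at 57415687 to 57416538 on chromosome 18, had 141 fragments and a ratio of 36.6 (30.8 to 43.2), and its summit was 5637 bp from that of the strongest peak. The interval of the strongest peak did not overlap that of the fourth, but both intervals cover the ChIP pileup only. The expected pileup was 3.85 fragments at both summits and was taken as fixed. Counting error of the control was left out, so the difference is not shown to be resolved.

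The other 6 peaks of the 10 with highest fold were spread over as many chromosomes. The peak at 1008560 to 1009886 on chromosome 15 had a ratio of 33.1 (27.1 to 40.0), and the peak at 8473685 to 8474414 on chromosome 7 had a ratio of 30.9 (25.6 to 37.0). On chromosome 2 the peak at 32313973 to 32315226 had a ratio of 29.3 (24.2 to 35.3), in a 1 Mb window of 12 peaks. The peaks at 3951395 to 3952448 on chromosome 11, 38886711 to 38887265 on chromosome 5 and 8699774 to 8700379 on chromosome 14 had ratios of 28.6, 28.1 and 27.5. Each of the 9 steps from one peak to the next in rank of fold was within counting error (exact conditional test of the pileups, two-sided, adjusted p = 0.89 for each of the 9). The order of adjacent ranks was therefore not resolved at this depth.

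**Figure D1:**
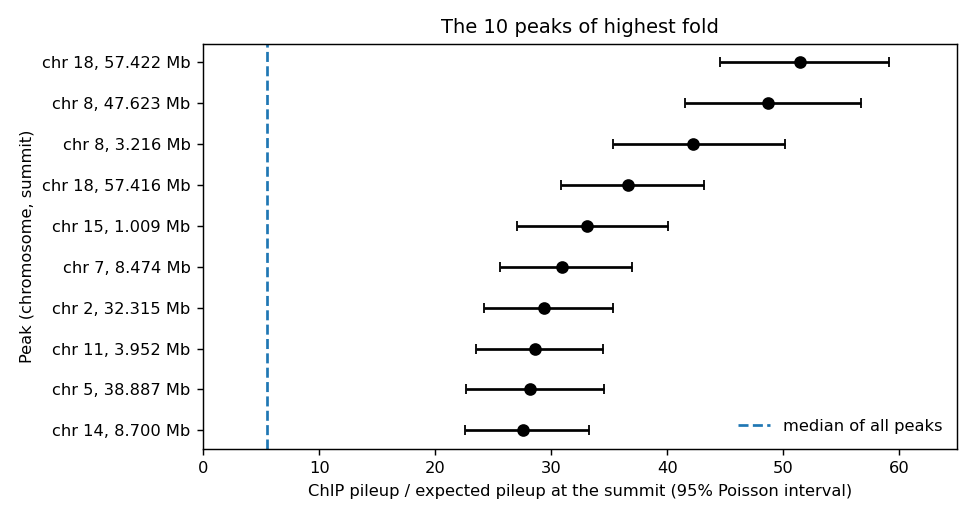
Ratio of ChIP pileup to expected pileup at the summit (x axis) for the 10 peaks of highest fold, labelled by chromosome and summit position in Mb. Points are the ratios, and bars are 95% Poisson intervals of the ChIP pileup with the expected pileup taken as fixed. The bars do not cover the selection of these peaks for high fold. The dashed line is the median ratio of all peaks, 5.52, and the peaks lie between 27.5 and 51.4.

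Most sites were far weaker than these. The caller's fold had a median of 4.52 (quartiles 3.92 and 5.49) and ranged from 1.73 to 41.0. Fold was below 6 in 81.8% of peaks, at least 10 in 779 peaks (2.48%) and at least 20 in 17 peaks. Without the pseudocount the median ratio was 5.52 (quartiles 4.74 and 6.82). Peaks were narrow, with a median width of 375 bp (quartiles 291 and 514 bp), and 1998 peaks (6.35%) had the smallest width of 246 bp, which equals the extended fragment length. Only 750 peaks (2.38%) were wider than 1000 bp and 29 were wider than 2000 bp. Wider peaks tended to have higher fold, with a Spearman correlation of 0.53 across peaks, which are not independent replicates. Width and fold both come from the same pileup, so the calling itself can give such a relation. The widest regions were not the strongest, and they were chosen after their values were seen. The peak at 6623613 to 6628330 on chromosome 14 spanned 4718 bp with a ratio of 9.23 (6.43 to 12.8), and the peak at 5112857 to 5117536 on chromosome 11 spanned 4680 bp with a ratio of 11.8 (8.97 to 15.3).

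At most peaks a control window exceeded the caller's genome-wide average, but seldom by much, and the median expected pileup was 3.43 fragments. This average, here and below, rests on the genome size given to the caller, which is not known here. In 5649 peaks, 17.96% (Wilson 95% interval 17.5% to 18.4%), the control did not exceed the genome-wide average of 3.08 fragments in any of the caller's windows. In 492 peaks, 1.56% (1.43% to 1.71%), the expected pileup was at least 2 times that average. It was at least 3 times the average in 26 peaks, of which 20 fell in 3 short stretches. On chromosome 13, 10 such peaks lay between 38797999 and 38856279, with expected pileups of 11.3 to 15.4 and ratios of 2.53 to 8.37. On chromosome 19, 7 lay between 43722540 and 43741397, with expected pileups of 9.38 to 17.3 and ratios of 3.02 to 10.6. On chromosome 15, 3 lay between 17745270 and 17754937. The highest control level was at 6400494 to 6400785 on chromosome 18, where 66.0 fragments were expected and 115 were found, a ratio of 1.74 (1.44 to 2.09). The median ratio of the 26 peaks was 3.55, against 5.52 in the rest. These peaks were picked for a high expected pileup, which divides the ratio. The caller's cutoff also admits lower ratios where more fragments are expected. The difference therefore follows at least in part from the selection.

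Peaks were concentrated toward the chromosome ends. The middle stretch of each chromosome was 33.3% of its length up to the last peak. Together these stretches held 12.4% of the peaks (Wilson 95% interval 12.01% to 12.7%). The interval treats peaks as independent and does not cover the spread between chromosomes. The middle stretch held less than an even share on 19 of the 20 chromosomes, with the lowest share, 6.35%, on chromosome 2. Chromosome 13 differed, with 41.5% (39.5% to 43.5%) of its 2300 peaks in the middle stretch, 51.3% in the last and only 7.22% in the first. Several chromosomes were lopsided: 73.6% of the peaks of chromosome 20 and 72.6% of those of chromosome 19 lay in the last stretch, while 68.0% of those of chromosome 15 and 67.8% of those of chromosome 6 lay in the first. The densest 25% of the 956 windows of 1 Mb held 57.2% of the peaks, against 34.0% on average and at most 34.4% in 200 random placements along the same chromosomes (permutation p = 0.005, the smallest these placements can give). The window with most peaks, 123, was 49000001 to 50000000 on chromosome 10, followed by 108 at 37000001 to 38000000 on chromosome 13. The median window held 21.5 peaks and 27 windows held 0. The longest run of windows with at most 2 peaks each was 14000001 to 20000000 on chromosome 19, with 5 peaks in 6 windows.

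**Figure D2:**
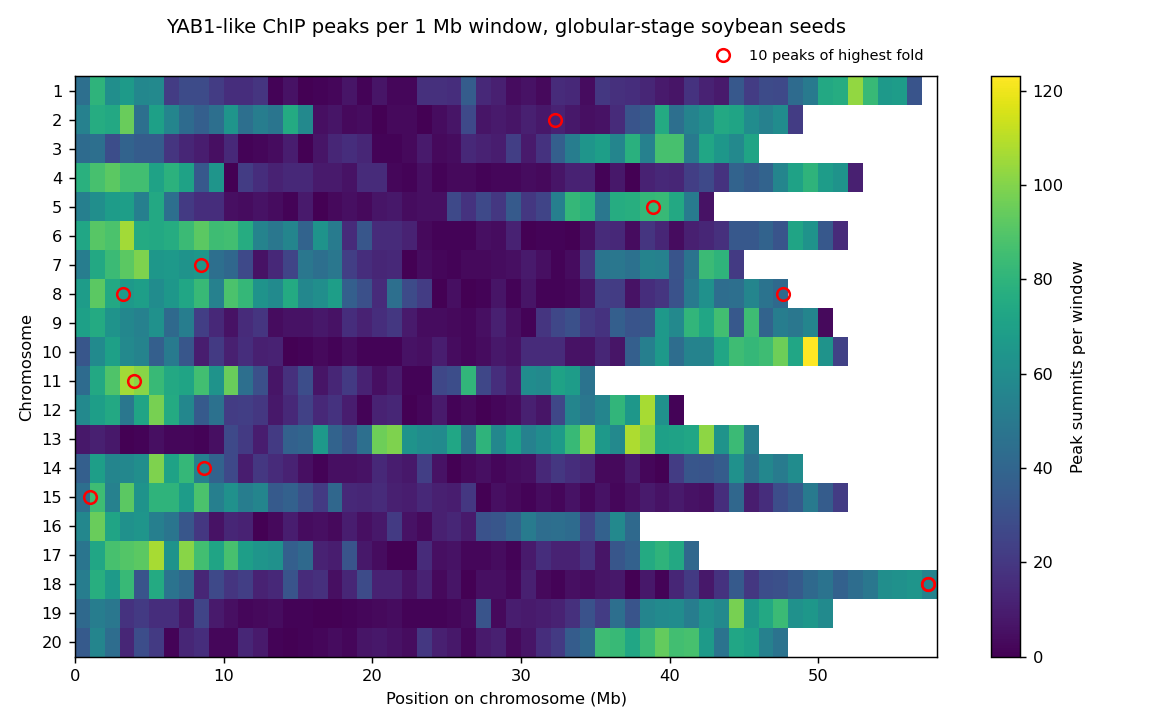
Number of peak summits in each 1 Mb window (colour scale) along the 20 chromosomes (rows; x axis, position in Mb), with red circles at the 10 peaks of highest fold; the circles of the strongest and the fourth strongest coincide at the end of chromosome 18. Counts are mostly highest toward the chromosome ends and reach 123 in 1 window of chromosome 10. On chromosome 13 they are low in the first stretch and high in the middle and last stretches.

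Median fold of the called peaks differed little with peak density. All peaks had passed the same cutoff of the caller, and fold was below 6 in 81.8% of the list. Medians therefore had little room to differ, and they cannot show whether binding strength varies with density. Median fold was 4.53 in the densest 25% of windows, here with ties, as all windows of at least 57 peaks (17923 peaks). In the windows at or below the median density (3858 peaks) it was 4.45, a difference of 0.0839 (permutation p = 0.0024). Single peaks were permuted, so this p-value ignores their grouping in windows, although neighbouring peaks were slightly alike in fold. The difference was 0.0295 among peaks with a −log10 q-value of at least 5 (permutation p = 0.14) and 0.0521 with windows of 2 Mb (permutation p = 0.054), so the call did not hold there. Median fold was 4.50 in the middle stretches (3867 peaks) and 4.53 in the remainder (27391 peaks), a difference that random permutation of the peaks often gave (permutation p = 0.34). Chromosomes ranged from 25.4 peaks per Mb on chromosome 18 to 50.2 on chromosome 13, with a mean of 33.4 ± 6.68 (SD, 20 chromosomes). Their median fold ranged only from 4.41 to 4.59. Across the 20 chromosomes, peaks per Mb had no detectable relation with median fold (Pearson r = 0.21, adjusted permutation p = 0.38; Spearman rho = 0.13, adjusted permutation p = 0.65) or with median width (r = 0.22, adjusted permutation p = 0.38; rho = 0.11, adjusted permutation p = 0.65). Without chromosomes 11 and 13, the farthest from the median density, r was 0.09 for fold and 0.05 for width. The share of peaks whose control did not exceed the genome-wide average fell with peak density. Pearson r was -0.80 (permutation p = 3e-05, adjusted 9e-05), Spearman rho was -0.88 (permutation p = 1e-05, the smallest 100000 permutations can give, adjusted 3e-05), and r was -0.83 without chromosomes 11 and 13. These 3 relations were computed as 1 family.

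Sites occurred in close groups. The median distance between neighbouring summits was 8.59 kb (quartiles 2.35 and 26.2 kb). Of 31238 neighbouring pairs on the chromosomes, 6973 (22.3%, Wilson 95% interval 21.9% to 22.8%) were within 2 kb of each other, against 10.8% ± 0.157 (SD of 1000 random placements within the same 1 Mb windows) and at most 11.2% (permutation p = 0.001, the smallest these placements can give). Chains of summits at most 2 kb apart numbered 5129 and took in 12102 peaks, 38.7% of those on chromosomes, against 20.2% ± 0.290 (SD) in 1000 random placements within 1 Mb windows (permutation p = 0.001). Of the chains, 1317 had 3 or more summits. The longest, chosen after its values were seen, had 12 summits between 41030822 and 41043865 on chromosome 9, with folds from 3.44 to 18.6. A chain of 9 lay between 39937056 and 39947299 on chromosome 7, with folds from 3.50 to 11.2. Median fold did not differ detectably between peaks in chains and single peaks, at 4.51 and 4.53 (permutation p = 0.64). The caller's cutoff limits this comparison too. When peaks within 500 bp of each other were merged, the share of neighbours within 2 kb was 12.7%, against 9.74% in random placements within 1 Mb windows and 10.8% within 100 kb windows. The share of merged peaks in chains was 23.5%, against 20.1% in placements within 100 kb windows.

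**Figure D3:**
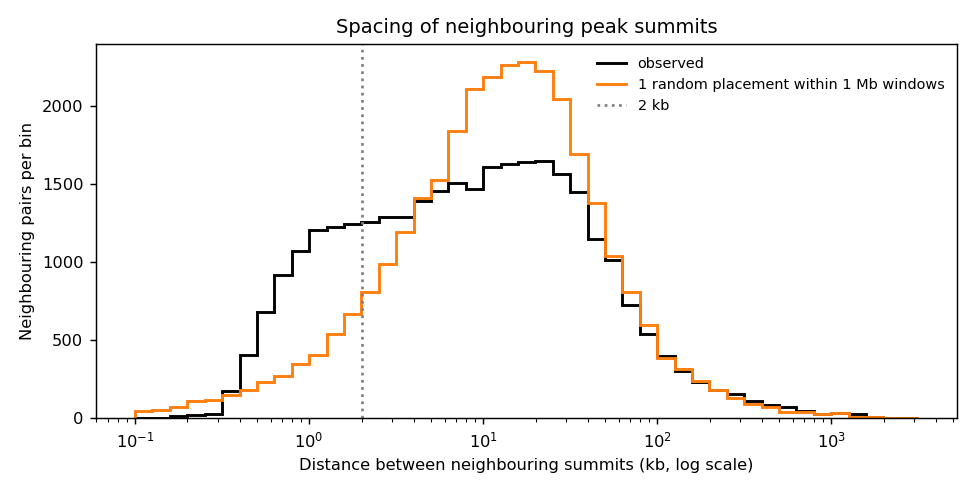
Distances between neighbouring peak summits (x axis, kb, log scale) and the number of neighbouring pairs in each distance bin (y axis), for the observed peaks (black) and 1 random placement of the summits within their 1 Mb windows (orange). The observed curve lies below the random one at distances under 316 bp, where randomly placed summits may fall although peaks of the list do not overlap. From 316 to 3981 bp, a range that includes 2 kb (dotted line), the observed curve lies above the random one. Of the observed pairs, 22.3% lie within 2 kb.

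Neighbouring sites were slightly alike in strength. Over 16614 pairs of neighbouring peaks within 10 kb, the Spearman correlation of fold was 0.07, above the highest of 1000 shuffles within chromosomes, 0.03 (permutation p = 0.001, the smallest these shuffles can give). Among the 100 peaks of highest fold, 4 neighbouring pairs lay within 10 kb of each other. Over 10000 shuffles of fold over all peaks, the count was 0.287 on average and at most 4 (one-sided permutation p = 0.0003). The pair on chromosome 18, described above, was among the 4 observed pairs and had been seen before this count was made. Without its 2 peaks, 3 pairs remained among the 98 others, against 0.285 on average and at most 3 in the shuffles (one-sided permutation p = 0.0019). The correlation is across peaks of 1 library, which are not independent replicates.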

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

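The peaks on unplaced scaffolds were flagged because they stood outside the comparisons along chromosomes, while having ChIP signal above the control as all peaks of the list do. They numbered 203, or 0.645% of the list, on 44 scaffolds, with 69 on scaffold 21 and 1 each on 25 scaffolds. Their median fold was 4.58, against 4.52 on the chromosomes, and the highest was 14.1. The control did not exceed the genome-wide average in 31.5% of them, against 17.9% on the chromosomes.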

How the results depend on the processing

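The number of peaks depended on the threshold: 31461 as deposited, 24119 at a −log10 q-value of at least 5, 30889 at a fold of at least 3, and 8183 at a −log10 q-value of at least 10. The list held no overlapping peaks to merge. The other alternatives, 32 in all, were chosen after seeing the data, and 29 kept the direction and the side of the threshold of the reported result, where there was a test. The 29 include 5 for the median ratio of pileups. That ratio had no test and could not change direction, because all called peaks lie above their expected pileup. The alternatives that were not kept concern the difference in median fold between dense and sparse windows, 0.0839 as reported. It was 0.0295 at a −log10 q-value of at least 5 (permutation p = 0.14), 0.0651 at 10 or more (permutation p = 0.21) and 0.0521 with 2 Mb windows (permutation p = 0.054), and the cause was not tested. The share of peaks in the densest 25% of windows ranged from 56.5% to 62.0% over 6 alternatives. The share of neighbours within 2 kb ranged from 7.88% (−log10 q-value of at least 10, against 3.22% in random placements) upward, with 12.7% after merging peaks within 500 bp; the same count was 10.6% for a distance of 1 kb and 39.0% for 5 kb. The correlation of fold between neighbours ranged from 0.04 (pairs within 50 kb) to 0.08 (−log10 p-value in place of fold) over 7 alternatives. The median ratio of pileups was 8.15 at a −log10 q-value of at least 10 and 4.52 with the caller's pseudocount. Of the 38 alternatives planned before the data were examined, 34 were not run, because they concern promoters, gene lists and motifs, which need a genome and annotation not used here. No paired analysis was possible because there was 1 peak list. Depth limits single peaks: the median pileup of 20 fragments has a counting interval of 12.2 to 30.9.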

Other observations

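The test of splitting and local density together was chosen only after the results of the separate tests were seen, and the patterns themselves were noticed in the list. The design gives no group that separates a biological explanation, so none was tested.

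Peaks were concentrated in part of the 1 Mb windows and sparse in the middle of 19 of 20 chromosomes. A candidate explanation is that fewer reads can be placed in sparse stretches, as in repeat-rich sequence, which predicts a lower control around sparse sites. The control did not exceed the genome-wide average in 36.0% (Wilson 95% interval 34.5% to 37.5%) of 3858 peaks in the sparser windows. In the densest 25% of windows, with ties, this held for 12.6% (12.1% to 13.1%) of 17923 peaks. The difference goes with this explanation, but how far below the average the control lay cannot be read from the expected pileups. By position the contrast was smaller, 30.2% in the middle stretches against 16.1% in the remainder. A higher yield of control chromatin from gene-rich, open regions would give the same difference, and a genome sequence with its annotation would be needed to separate them.

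Summits lay closer together than in random placements within 1 Mb windows. The placements used whole windows, including any sequence where reads cannot be placed. They therefore do not cover unevenness finer than the windows. Merging peaks within 500 bp removed 3106 peaks and lowered the ratio to random placement from 2.07 to 1.31, or to 1.18 with placement within 100 kb windows, but merging deletes the closest pairs by construction, so this does not show that the caller had split broad regions. Splitting at that distance was not the whole cause, because 12.7% of merged neighbours stayed within 2 kb, above the highest random value of 10.4%. Density that varies between 100 kb windows gave at most 12.8%, against the 22.3% observed, and merging and 100 kb windows together gave at most 11.3%, against 12.7%. Sites grouped at single genes or shared regulatory regions, and uneven placement of reads within the windows, stay open, as untested.

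Neighbouring peaks had slightly similar fold. A shared local control level could produce this. Both peaks had the expected pileup at its floor in 953 pairs. ChIP pileups of these pairs correlated at 0.112, just above the highest of 1000 shuffles at 0.109. Control levels below the floor cannot be read, and neighbours may share them. These pairs therefore cannot set a shared control level aside. Fragments counted in both peaks could also produce similar fold. However, 13317 pairs more than 1 kb apart gave a correlation of 0.0611, above the highest shuffle at 0.0283. The size of the correlation is small, and local differences in chromatin accessibility or in fragment recovery stay open, as untested.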
